A study of Oryza sativa and Hordeum vulgare with 24 samples.

How the data were processed

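The libraries came from barley accession XZ26, a Tibetan wild barley, and from the japonica rice cultivar Nipponbare. Seedlings stood in nutrient solution, where NaCl was raised daily to 100 mM, and control plants received 0 mM. Roots and the latest fully expanded leaves, the tissue the labels call shoot, were taken after 7 d, with 3 biological replicates for each species, tissue and treatment. Per the labels, RNA was extracted with TRIzol and RNeasy columns, enriched for polyadenylated RNA with poly-T beads, made into TruSeq libraries and sequenced as paired 100-base reads on a HiSeq2500. The submitters' processing notes state that adapters, low-quality bases and short reads were removed and that TopHat aligned the rest to the Ensembl Genomes sequences of each species. Strand use and the treatment of reads that map to several places are not given in the sources used here, so values of multigene families and of overlapping genes are uncertain.

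The deposited tables give FPKM per gene and library as computed by the authors, and no counts were in use. They also hold the authors' log2 fold change and a mark for the genes the authors called, which served only as an alternative. A percent GC column in the deposited barley tables was not used. The authors' criterion, per the labels, was a fold change above 2 with a false discovery limit that is cut off in the label text. The rice tables list 55986 genes and those of barley list 26066. Positions, descriptions, Gene Ontology terms, InterPro names and Arabidopsis identifiers were those in the deposited tables. An informative description was present for 57.1% of rice genes and 18.4% of barley genes.

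Every nonzero value of a gene was, within a tolerance of 0.02 reads, a whole multiple of a gene-specific step in each library, for 35685 rice genes and 22694 barley genes. Fragments per gene were recovered from these steps, and the FPKM denominator was 2 times the fragments on genes. The median length implied by FPKM was 499 bases in rice and 489 in barley, against a median genomic span of 3354 and 3081 bases. FPKM values are therefore compared within a gene and not between genes.

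Salt was compared with control within each species and tissue on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend in the variance. Genes with a mean of at least 1 FPKM over the 6 libraries of a table were tested. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 and an absolute log2 fold change above 1. The added 1 understates the change of genes with low values. SE is the limma standard error of the log2 fold change. Shoot minus root was tested as the treatment by tissue interaction over the 12 libraries of a species. Each adjusted p of a gene below comes from limma with BH adjustment within its comparison.

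The test, thresholds, filter, 31 gene lists and most alternatives were fixed before the data were examined. List members came from the description where that was informative and from InterPro names otherwise. The lists cover ion and water transport, proton pumps, abscisic acid, LEA proteins, osmolytes, reactive oxygen, peroxidases, glutathione transferases, photosynthesis, chlorophyll, nitrogen, phosphate and metals, ribosomes, cell walls, phenylpropanoids, heat shock, jasmonate, ethylene with auxin and cytokinin, pathogenesis-related proteins, 5 transcription factor families, splicing factors, lipid transfer, the Casparian strip, cell division, senescence and housekeeping. The fixed patterns also took in look-alike members. These are plastocyanin-like genes under photosynthesis, soluble pyrophosphatases under proton pumps, genes with methionine or cystathionine in the name under pathogenesis-related proteins (through the word thionin), and a few genes under aquaporins, NAC, AP2/ERF, nitrogen and senescence. An added membership drops them and gives the proton pumps H+ pyrophosphatases and V-type ATPase subunits that the pattern missed. A first form of it, which also added ATPase subunits named for both F and V types, left the proton pump list of barley leaves called and called jasmonate in rice roots, and was set aside because such subunits can be mitochondrial. Rice identifiers of the RAP type in the planned lists were not matched to the locus names of the tables. Lists were tested with camera in limma at the preset correlation of 0.01, with BH adjustment over all lists and the 4 tables together. With a correlation estimated from the data no list was called in any table, and that adjusted p stands beside each call. Member counts "adjusted over the list alone" use BH within the list.

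Gene Ontology terms of 10 to 500 members were tested with 1-sided Fisher tests, separately for higher and lower genes, with BH within a table. Backgrounds were the tested genes with a term: 13337 in rice roots, 12018 in rice leaves, 9724 in barley roots and 8666 in barley leaves. Rice and barley genes were paired indirectly through 1 shared Arabidopsis identifier, which 32261 rice and 2266 barley genes carry. This gave 1609 pairs. List medians of the species were compared by 100000 permutations of list members between the species, whose smallest possible p is 1.0e-05, with BH adjustment. Genes are not independent replicates, so correlations across genes and these permutations describe gene sets and not plants.

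Genes named in the text were drawn from a rule fixed in code. It took the 8 largest changes each way among called genes with non-overlapping groups, a mean of at least 5 FPKM and an informative description. It also took the called member with the lowest adjusted p each way from each list with at least 2 called members, the rice genes named in the lists, barley Na+ and K+ transport members with at least 5 FPKM, and the 5 largest interactions each way. The rule gave 226 results, 70 in rice roots, 66 in rice leaves, 57 in barley roots and 33 in barley leaves, of which the text names part, chosen per gene group, and 1 item is not reported here. Other Na+ and K+ transport members and the rice and barley pairs were named after their values had been seen.

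Alternatives fixed beforehand were a filter at 5 FPKM, no filter, no fold threshold, an adjusted p below 0.01, an added 0.1 in place of 1, quantile normalization, a replicate block, both tissues in 1 fit, each library left out, an estimated list correlation and the authors' calls. Added after the data were seen were limma voom on recovered fragments, median-ratio scaling, list membership by description alone and without look-alike members, the lists and the species comparison under the remaining settings, and list medians relative to all genes. In the comparison of settings, a count within a factor of 1.5 of the main count is the same. A gene or list is reversed only where the main or the alternative result is called and the direction differs.

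In a self-test with planted increases in rice root values, limma with these thresholds recovered 100.0% of changes at a fold of 4, 97.5% at 3 and 35.0% at 2, and called 0.005% of 19497 simulated genes falsely. In 13126 genes simulated for barley leaves it recovered 97.5%, 95.0% and 35.0%, but real recovery with control replicate 3 is unknown. For the interaction it recovered 5.0%, 47.5% and 100.0% at folds of 2, 3 and 4 in rice and 12.5%, 60.0% and 92.5% in barley. Smaller differences are mostly missed. The term test found 3 of 3 planted terms in rice and barley roots, with 0 and 1 unrelated terms. In rice roots camera called the planted list and 0 of 20 random lists, leaving correlated genes untested. Transcript usage was not analysed, as no transcript-level file was used. Tables, terms and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.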

Results

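The series asks why salt tolerance differs between barley and rice, and it measures messenger RNA in roots and in the latest fully expanded leaves of both species after 7 d at 100 mM NaCl or 0 mM. Each of the 8 combinations of species, tissue and treatment had 3 biological replicates, 24 libraries in all. Fragments on genes, recovered from the FPKM values, numbered 33.6 to 53.8 M per library in rice roots, 25.8 to 41.0 M in rice control leaves and 23.3 to 27.3 M in rice salt leaves. In barley they numbered 24.9 to 30.1 M in control roots, 23.6 to 30.3 M in salt roots, 28.1 to 36.5 M in control leaves and 32.1 to 51.7 M in salt leaves. Between 18662 and 19789 genes reached 1 FPKM in a rice root library and 16271 to 17859 in a rice leaf library. In barley, 15019 to 15130 genes did so in a root library and 12621 to 13318 in a leaf library. The largest gene by fragments, MLOC_64679 or MLOC_76546, took 2.2 to 5.3% of the fragments of a barley leaf library.

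The first question is which genes change in rice roots after 7 d of salt. The Na+ transporter genes OsHKT1;5 and OsHKT2;1 and the nicotianamine synthase genes NAS1 and NAS2 fell in salt. So did 57 of 115 cell wall genes, 13 of 33 genes of the aquaporin list, 25 of 62 phenylpropanoid and lignin genes and 7 of 20 nitrogen genes, while 6 of 47 splicing factor genes rose. Most members of most of these groups were not called, and with an estimated correlation no list was called in rice roots (camera adjusted p = 0.629 to 0.745 for these lists). In total 1473 genes rose and 2463 fell of 19715 tested.

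Among genes of ion and water movement, OsHKT1;5 (LOC_Os01g20160, chromosome 1, 11457931 to 11462418), known to retrieve Na+ from the xylem, fell from 6.41 ± 0.766 to 0.443 ± 0.289 FPKM (mean ± SD, n = 3), a log2 fold change of -2.37 (SE 0.19, adjusted p = 2.7e-05). OsHKT2;1 (LOC_Os06g48810, chromosome 6, 29537936 to 29540221), known for Na+ uptake, fell from 4.38 ± 0.464 to 0.0136 ± 0.0155 FPKM (log2 fold change -2.40, SE 0.16, adjusted p = 1.1e-05). The K+ channel gene AKT1 (LOC_Os01g45990) fell from 143.6 ± 20.1 to 30.2 ± 4.73 FPKM (-2.21, SE 0.16, adjusted p = 1.6e-05), and the K+ transporter gene LOC_Os04g32920 from 113.3 ± 15.1 to 14 ± 2.41 FPKM (-2.94, SE 0.16, adjusted p = 5.3e-06). The K+ transporter gene LOC_Os07g47350 rose from 416.7 ± 7.78 to 1076 ± 12.1 FPKM (1.37, SE 0.09, adjusted p = 1.1e-05). Of 28 Na+ and K+ transport genes tested, 1 rose, 7 fell and 20 were not called (median -0.35, list adjusted p = 0.344). OsHKT1;3 (LOC_Os02g07830) had a log2 fold change of -0.99 (adjusted p = 0.00177), short of the fold threshold. OsHKT1;4 (LOC_Os04g51830) lay at 0.245 FPKM in control and 0.103 in salt and was not tested. The largest increase named here was that of LOC_Os05g31730 (chromosome 5, 18415009 to 18418966), described as a cation:proton antiporter, from 0.406 ± 0.37 to 57.8 ± 10.5 FPKM (5.40, SE 0.22, adjusted p = 2.3e-06). Of 33 genes of the aquaporin list, 13 fell and 0 rose (median -0.65, -0.55 relative to all genes; camera adjusted p = 8.7e-04, 0.745 with an estimated correlation). The aquaporin LOC_Os02g44080 (chromosome 2, 26602492 to 26603789) fell from 2367 ± 255.5 to 103.5 ± 22.3 FPKM (-4.52, SE 0.16, adjusted p = 1.9e-06). By description 5 of the 33 are not aquaporins, and without them 12 of 28 fell (adjusted p = 9.7e-05, 0.63 with an estimated correlation). Of 26 genes of the proton pump list, 5 fell and 0 rose (median -0.55, -0.45 relative to all genes; camera adjusted p = 0.0148, 0.629 with an estimated correlation). Of these 26, 6 are soluble pyrophosphatases and not pumps, 2 of them among the 5 that fell. With those dropped and 7 H+ pyrophosphatase or V-type ATPase genes added, 5 of 27 fell and 1 rose (median -0.47, adjusted p = 0.0305, 0.533 with an estimated correlation).

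Of 115 genes for wall loosening and synthesis, 57 fell and 7 rose (median -0.94, -0.84 relative to all genes; camera adjusted p = 3.7e-05, adjusted p = 0.745 with an estimated correlation). Of 97 class III peroxidase genes, 51 fell and 7 rose (median -1.12, -1.01 relative to all genes; adjusted p = 4.6e-06, adjusted p = 0.629 with an estimated correlation). Of 62 phenylpropanoid and lignin genes, 25 fell and 3 rose (median -0.79, -0.68 relative to all genes; adjusted p = 8.7e-04, adjusted p = 0.629 with an estimated correlation). The laccase gene LOC_Os12g15920 fell from 341.1 ± 38.8 to 31.8 ± 1.74 FPKM (log2 fold change -3.38, SE 0.12, adjusted p = 1.9e-06) and the peroxidase gene LOC_Os05g04500 from 13.1 ± 1.21 to 0.159 ± 0.151 FPKM (-3.61, SE 0.17, adjusted p = 3.2e-06). Members that rose were the expansin gene LOC_Os10g39640 (2.56), the dirigent gene LOC_Os03g59440 (2.25) and the peroxidase gene LOC_Os09g29490 (1.49). Of 159 cell division genes, 52 fell and 3 rose (median -0.56, -0.45 relative to all genes; adjusted p = 4.0e-04, adjusted p = 0.753 with an estimated correlation). A tubulin gene, LOC_Os01g18050, fell from 1986 ± 91 to 117.8 ± 30.1 FPKM (-4.10, SE 0.18, adjusted p = 2.6e-06), and a sucrose synthase gene, LOC_Os03g28330, from 8089 ± 403.9 to 1509 ± 143.2 FPKM (-2.42, SE 0.11, adjusted p = 2.6e-06).

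The nicotianamine synthase genes NAS1 (LOC_Os03g19427, chromosome 3, 10928201 to 10929613) and NAS2 (LOC_Os03g19420, chromosome 3, 10925187 to 10926668) make a chelator known for iron transport. NAS1 fell from 80.4 ± 8.81 to 2.09 ± 0.682 FPKM (log2 fold change -4.74, SE 0.19, adjusted p = 2.3e-06) and NAS2 from 88.9 ± 9.08 to 2.58 ± 1.62 FPKM (-4.73, SE 0.28, adjusted p = 6.7e-06). Of 20 nitrogen genes, 7 fell and 1 rose (median -0.66, -0.56 relative to all genes; camera adjusted p = 0.0203, adjusted p = 0.745 with an estimated correlation). A nitrate transporter gene, LOC_Os02g38230, fell from 77.4 ± 8.09 to 7.83 ± 1.83 FPKM (-3.17, SE 0.18, adjusted p = 5.3e-06). The peptide transporter gene LOC_Os10g40600 fell from 59.1 ± 11.2 to 0.623 ± 0.263 FPKM (-5.21, SE 0.19, adjusted p = 1.9e-06). Of 47 splicing factor genes, 6 rose and 1 fell (median 0.43, 0.53 relative to all genes; adjusted p = 9.3e-05, adjusted p = 0.745 with an estimated correlation). The splicing factor gene LOC_Os01g03060 rose from 229.8 ± 26.1 to 815.2 ± 222.2 FPKM (1.80, SE 0.18, adjusted p = 8.9e-05).

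The remaining lists of rice roots were not called. In stress protection, 3 of 16 LEA and dehydrin genes rose and 2 fell (camera adjusted p = 0.994), 3 and 5 of 63 abscisic acid genes (0.637) and 7 and 5 of 32 osmolyte genes (0.605). The counts were 5 and 4 of 46 reactive oxygen genes (0.939), 5 and 4 of 60 glutathione transferase genes (0.56) and 18 and 14 of 151 heat shock genes (0.215). Among them the trehalose-6-phosphate synthase gene LOC_Os02g54820 (log2 fold change 1.54), the phosphatase 2C gene LOC_Os04g25570 (1.96) and the dehydrin gene LOC_Os11g26790 (1.70) rose, and the ascorbate peroxidase gene APX2 (LOC_Os07g49400) fell (-1.46). In hormones and defence, 2 of 21 jasmonate genes rose and 7 fell (median -0.70, adjusted p = 0.0513), 12 and 24 of 132 ethylene, auxin and cytokinin genes (0.6), and 18 and 32 of 121 genes of the pathogenesis-related list (0.38), 24 of which matched only through names such as methionine (16 and 29 of 97 without them, 0.374). The auxin efflux gene LOC_Os09g31478 rose (2.43) and the lipoxygenase gene LOC_Os03g52860 fell (-2.42). Among transcription factors, 11 WRKY genes rose and 4 fell of 65 (adjusted p = 0.115), 4 and 7 of 67 NAC genes (0.755), 12 and 10 of 99 genes of the AP2/ERF list (0.557), 14 and 23 of 156 MYB genes (0.827) and 4 and 3 of 37 bZIP genes (0.804). The NAC gene LOC_Os03g60080, annotated as NAC67 (1.98), and OsWRKY48 (LOC_Os05g40060, 2.19) were among those that rose. The photosynthesis list had 55 genes, of which 8 rose and 18 fell (median -0.41, adjusted p = 0.215), but 31 of them, including all 18 that fell, are plastocyanin-like genes and not genes of photosynthesis. Of the other 24 genes 7 rose and 0 fell (median 0.37, adjusted p = 0.00341, adjusted p = 0.533 with an estimated correlation). In metabolism, 1 and 1 of 9 chlorophyll genes (0.898), 4 and 7 of 33 phosphate and metal genes (0.994), 2 and 6 of 117 ribosomal genes (0.072), 0 and 9 of 51 genes of the senescence list (0.388) and 4 and 12 of 54 housekeeping genes (0.24). The osmolyte list had a median of 0.17 and a mean of -0.08. Lipid transfer proteins had only 2 genes tested, 1 of which fell, and the Casparian list had 0 members in rice. The ribosomal list was called as lower under quantile normalization (adjusted p = 0.0262) and without salt replicate 2 (0.0307). The jasmonate list was called as lower under median-ratio scaling (0.0445) and without control replicate 2, salt replicate 1 or salt replicate 3 (0.0427, 0.0357 and 0.0435). Member counts in rice roots were the same when adjusted over the list alone.

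In rice roots the values of salt and control did not overlap in 11990 genes (60.8%), against 10% by chance. Quantile normalization moved the all-gene median from -0.105 to 0.028 and gave 1907 genes higher and 1955 lower, median-ratio scaling gave 1783 and 2121, and the called lists kept their direction under both.

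The second question is which genes change in the rice leaf. In salt 18 of 27 dehydrin and other LEA genes rose, with 31 of 59 WRKY genes, 24 of 49 NAC genes and 55 of 156 heat shock genes, and 15 of 53 photosynthesis genes fell while 1 rose, plastocyanin-like genes left aside. With an estimated correlation no list was called in rice leaves (camera adjusted p = 0.629 to 0.753 for these lists). In total 3654 genes rose and 957 fell of 17640 tested.

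Of 27 LEA and dehydrin genes, known for protecting cells that lose water, 18 rose and 0 fell in rice leaves (median 1.89, 1.56 relative to all genes; camera adjusted p = 2.1e-06, adjusted p = 0.649 with an estimated correlation). The dehydrin genes LOC_Os11g26790 (chromosome 11, 14878878 to 14880171) and LOC_Os11g26780 rose from 37.5 ± 7.13 to 3175 ± 144.1 FPKM (log2 fold change 6.38, SE 0.19, adjusted p = 2.4e-06) and from 1.67 ± 0.69 to 239.7 ± 45.1 FPKM (6.51, SE 0.25, adjusted p = 5.7e-06). A LEA group 3 gene, LOC_Os05g46480, rose from 7.45 ± 1.89 to 526.9 ± 109.8 FPKM (5.97, SE 0.25, adjusted p = 5.7e-06). The largest increase named here was that of the jacalin gene LOC_Os01g24710 (chromosome 1, 13902127 to 13903703), from 1.97 ± 0.365 to 323.8 ± 115.9 FPKM (6.72, SE 0.28, adjusted p = 5.7e-06). Of 70 abscisic acid genes, 22 rose and 3 fell (median 0.46, list adjusted p = 0.42). The phosphatase 2C gene LOC_Os06g48300 rose from 5.6 ± 1.31 to 194.7 ± 41.1 FPKM (4.89, SE 0.25, adjusted p = 1.3e-05), and NCED1 (LOC_Os02g47510), known for abscisic acid synthesis, fell (-2.12, adjusted p = 0.00376). Of 29 osmolyte genes, 11 rose and 2 fell (median 0.50, list adjusted p = 0.305), with the raffinose synthase gene LOC_Os06g07600 (3.27) among those that rose.

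Of 70 genes of the photosynthesis list, 18 fell and 8 rose in rice leaves (median -0.50, -0.82 relative to all genes; camera adjusted p = 4.9e-07, 0.745 with an estimated correlation). Without its 17 plastocyanin-like genes, 15 fell and 1 rose of 53 (median -0.74, adjusted p = 2.2e-11, 0.63 with an estimated correlation). The list as fixed held 19.91 ± 1.03% of fragments in control leaves and 8.81 ± 2.42% in salt leaves (n = 3), and without the plastocyanin-like genes 19.82 ± 1.05% and 8.67 ± 2.45%. A Rubisco small subunit gene, LOC_Os12g19470, fell from 1025 ± 147.5 to 277.2 ± 97.1 FPKM (log2 fold change -1.93, SE 0.26, adjusted p = 9.2e-04), and the glyceraldehyde-3-phosphate dehydrogenase gene LOC_Os04g38600 fell (-2.01). The stay-green gene LOC_Os09g36200, known for a part in chlorophyll breakdown, rose from 10.9 ± 1.63 to 95.3 ± 18.7 FPKM (3.01, SE 0.22, adjusted p = 5.5e-05), and the isocitrate lyase gene LOC_Os07g34520 from 9.28 ± 3.85 to 678.8 ± 145.4 FPKM (6.10, SE 0.32, adjusted p = 1.4e-05). Of 12 chlorophyll genes 3 rose and 0 fell (list adjusted p = 0.939). Of 41 genes of the senescence list 6 rose and 1 fell (0.43), 4 and 0 without 7 look-alike members. Of 116 ribosomal genes, 8 rose and 0 fell (median 0.50, 0.17 relative to all genes; adjusted p = 0.00217, adjusted p = 0.853 with an estimated correlation), and under median-ratio scaling this list was not called (adjusted p = 0.203).

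Among the largest decreases named in rice leaves were those of a reductase and a metal transporter gene. The ferric-chelate reductase gene LOC_Os04g48930 (chromosome 4, 28993724 to 28996525) fell from 132.1 ± 39.3 to 0.672 ± 0.152 FPKM (log2 fold change -6.27, SE 0.26, adjusted p = 5.7e-06). The metal transporter gene LOC_Os07g15460, annotated as Nramp6, fell from 175.3 ± 40.5 to 1.51 ± 0.395 FPKM (-6.12, SE 0.24, adjusted p = 5.7e-06). The bHLH gene LOC_Os01g72370 fell from 247.6 ± 52.6 to 1.86 ± 0.799 FPKM (-6.46, SE 0.27, adjusted p = 5.7e-06). An aminotransferase gene, LOC_Os01g09700, fell from 334.7 ± 92 to 2.83 ± 3.07 FPKM (-6.83, SE 0.62, adjusted p = 1.5e-04). Of 23 phosphate and metal genes, 8 rose and 7 fell (list adjusted p = 0.339), and the Gene Ontology term iron ion binding was enriched among genes that rose (114 against 77.0 expected, Fisher test with BH adjusted p = 3.4e-04). Of 24 nitrogen genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.42), with the glutamine synthetase gene LOC_Os03g50490 (5.37) rising and the nitrite reductase gene LOC_Os01g25484 (-1.88) falling.

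Of 34 Na+ and K+ transport genes in rice leaves, 15 rose and 5 fell (16 and 5 adjusted over the list alone; median 0.85, list adjusted p = 0.305). The outward K+ channel gene SKOR (LOC_Os06g14030) rose from 4.74 ± 0.725 to 78.9 ± 12 FPKM (log2 fold change 3.80, SE 0.21, adjusted p = 1.7e-05), and the K+ transporter gene LOC_Os06g15910, which fell in roots (-1.49), rose in leaves (3.13). OsHKT1;1 (LOC_Os04g51820) rose from 3.93 ± 0.578 to 9.9 ± 4.64 FPKM (1.07, SE 0.31, adjusted p = 0.0269). That call ended under median-ratio scaling (0.75, adjusted p = 0.107) and without salt replicate 1 (0.74, adjusted p = 0.0237), control replicate 1 (1.16, 0.0645), control replicate 2 (1.05, 0.0832) or control replicate 3 (0.99, 0.0962). Over all alternatives the log2 fold change ran from 0.65 to 1.31 with adjusted p up to 0.151. OsHKT1;3 (LOC_Os02g07830) fell from 18.5 ± 4.86 to 3.92 ± 1.27 FPKM (-1.99, SE 0.28, adjusted p = 0.00116), and OsHKT2;3 (LOC_Os01g34850) fell (-1.51, adjusted p = 0.00532). OsHKT2;4 (LOC_Os06g48800) was not called (-0.85, adjusted p = 0.0228). The Na+/H+ exchanger gene LOC_Os12g44360 was not called in leaves (0.73, adjusted p = 0.0181) or roots (0.31, adjusted p = 0.0683). Of 30 genes of the proton pump list, 11 rose and 0 fell (median 0.63, 0.31 relative to all genes; camera adjusted p = 0.0203, adjusted p = 0.629 with an estimated correlation), among them the plasma membrane ATPase gene LOC_Os03g48310, from 3.71 ± 0.727 to 48 ± 6.25 FPKM (3.38, SE 0.21, adjusted p = 2.6e-05). With 7 soluble pyrophosphatase genes, 3 of which rose, replaced by 7 H+ pyrophosphatase or V-type ATPase genes, 11 of 30 rose again (adjusted p = 0.0356, 0.63 with an estimated correlation). Of 30 genes of the aquaporin list, 6 rose and 2 fell (adjusted p = 0.605), 5 and 2 without 5 look-alike members.

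Of 59 WRKY genes, 31 rose and 0 fell (33 and 0 adjusted over the list alone; median 1.29, 0.97 relative to all genes; camera adjusted p = 0.00715, adjusted p = 0.753 with an estimated correlation). Of 49 NAC genes, 24 rose and 2 fell (25 and 2 adjusted over the list alone; median 1.17, 0.85 relative to all genes; adjusted p = 0.0141, adjusted p = 0.745 with an estimated correlation). OsWRKY23 (LOC_Os01g53260) rose from 1.02 ± 0.253 to 23.8 ± 1.55 FPKM (log2 fold change 3.63, SE 0.20, adjusted p = 1.7e-05) and the NAC gene LOC_Os11g03300 from 1.1 ± 0.628 to 50.1 ± 1.54 FPKM (4.64, SE 0.25, adjusted p = 1.4e-05). Of 156 heat shock genes, 55 rose and 6 fell (median 0.64, 0.32 relative to all genes; adjusted p = 0.0169, adjusted p = 0.629 with an estimated correlation), with the DnaJ gene LOC_Os01g42190 (4.39) among those that rose. Of 60 cell wall genes, 24 rose and 3 fell (25 and 3 adjusted over the list alone; median 1.16, 0.84 relative to all genes; adjusted p = 0.0478, adjusted p = 0.853 with an estimated correlation), with the polygalacturonase gene LOC_Os05g50260 (3.99) rising. This wall list was not called without control replicate 1, control replicate 3, salt replicate 1 or salt replicate 2 (adjusted p = 0.067, 0.0772, 0.316 and 0.0673).

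The other lists of rice leaves were not called. Of 41 phenylpropanoid genes, 17 rose and 2 fell (21 and 2 adjusted over the list alone; median 1.26, adjusted p = 0.0637), and the list was called under median-ratio scaling (0.0162), under quantile normalization (0.00993), without control replicate 1 (0.0484) and without salt replicate 3 (2.3e-04). Of 91 genes of the pathogenesis-related list, 38 rose and 4 fell (40 and 4 adjusted over the list alone; median 0.67, adjusted p = 0.0807), with the thaumatin gene LOC_Os01g62260 (log2 fold change 5.74) rising, and the list was called under median-ratio scaling (0.0224), under quantile normalization (0.0147) and without salt replicate 3 (0.00262). Without 24 genes that matched only through names such as methionine, 33 of 67 rose and 4 fell (adjusted p = 0.0496, adjusted p = 0.822 with an estimated correlation). Of 49 class III peroxidase genes 18 rose and 6 fell (18 and 8 adjusted over the list alone), with a median of 0.72, a mean of 0.65 and a camera direction below other genes (adjusted p = 0.994). Of 47 reactive oxygen genes 15 rose and 3 fell (0.339), of 48 glutathione transferase genes 17 and 3 (18 and 3 adjusted over the list alone; 0.624), and of 20 jasmonate genes 6 and 3 (8 and 3 adjusted over the list alone; 0.605). The counts were 30 and 13 of 109 ethylene, auxin and cytokinin genes (31 and 13 adjusted over the list alone; 0.874). Of 84 genes of the AP2/ERF list 22 rose and 1 fell (0.305), of 135 MYB genes 41 and 8 (0.6) and of 33 bZIP genes 11 and 3 (0.298). Of 47 splicing factor genes 5 rose and 1 fell (4 and 1 adjusted over the list alone; 0.847) and of 53 housekeeping genes 11 and 4 (0.981). Of 121 cell division genes 17 rose and 13 fell (0.17), and this list was called below other genes without salt replicate 1 (0.0379). Lipid transfer proteins had 1 gene tested, not called. The jasmonate methyltransferase gene LOC_Os06g21820 (4.78) and the U2AF splicing factor gene LOC_Os09g31482 (2.15) rose, and the serine-arginine matrix gene LOC_Os06g46149 fell (-3.56).

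In rice leaves 9377 genes (53.2%) had no overlap between salt and control, against 10% by chance, and the all-gene median was 0.321. Median-ratio scaling moved that median to -0.007 and the calls to 2425 higher and 1832 lower, quantile normalization gave 2107 and 2098. The medians of the aquaporin (0.13 to -0.25), chlorophyll (0.21 to -0.08), nitrogen (0.05 to -0.27), phosphate and metal (0.09 to -0.29), hormone (0.35 to -0.03), splicing (0.33 to -0.03) and cell division (0.15 to -0.18) lists changed sign under median-ratio scaling.

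**Figure D1:**
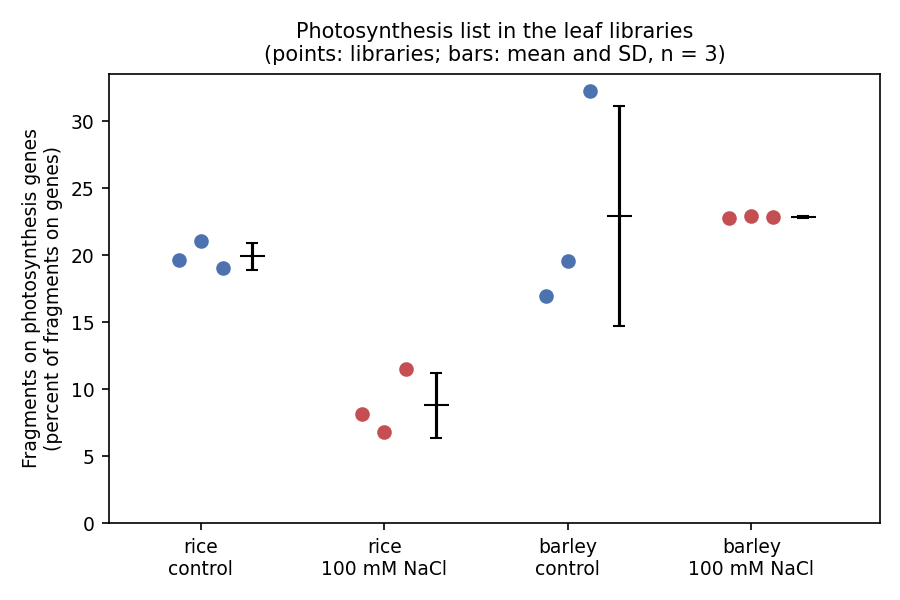
Percent of fragments on genes of the photosynthesis list as fixed in each leaf library of rice and barley, control and salt (points are libraries, bars mean and SD, n = 3). The rice salt libraries lie below the rice control libraries, and barley control replicate 3 lies above the other barley libraries.

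The third question is which genes change in barley roots. In salt 7 of 42 genes of the lipid transfer list, 5 of 34 phenylpropanoid genes and 12 of 107 peroxidase genes rose, and 3, 2 and 4 fell. With an estimated correlation none of these lists was called (camera adjusted p = 0.527, 0.527 and 0.745). NAAT-A and 3 nicotianamine synthase genes fell. In total 226 genes rose and 169 fell of 15171 tested.

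The largest decreases named in barley roots were those of transporter, dioxygenase and aminotransferase genes. NAAT-A (MLOC_4361, chromosome 1, 402035382 to 402038707), known for phytosiderophore synthesis, fell from 31.4 ± 7.75 to 0.144 ± 0.0582 FPKM (log2 fold change -4.80, SE 0.18, adjusted p = 4.3e-06). The nicotianamine synthase genes MLOC_3754, MLOC_56153 and MLOC_78101 fell from 26 ± 10.1 to 0.262 ± 0.163 FPKM (-4.36, adjusted p = 3.8e-05), from 31.2 ± 13.1 to 1.23 ± 0.325 FPKM (-3.79, adjusted p = 8.5e-05) and from 98.4 ± 39 to 8.04 ± 0.417 FPKM (-3.39, adjusted p = 8.5e-05). The dioxygenase gene MLOC_80402 (chromosome 4, 519753407 to 519755262) fell from 943.1 ± 252.1 to 21.8 ± 8.77 FPKM (-5.41, SE 0.28, adjusted p = 2.9e-05), and the dioxygenase gene MLOC_1079 from 287.5 ± 78.7 to 10.1 ± 5.55 FPKM (-4.78, SE 0.34, adjusted p = 1.2e-04). The major facilitator genes MLOC_56629 (chromosome 4, 520274973 to 520281404) and MLOC_70963 fell from 396.4 ± 82.8 to 7.2 ± 4.98 FPKM (-5.77, SE 0.40, adjusted p = 1.0e-04) and from 43 ± 11.3 to 1.14 ± 0.985 FPKM (-4.42, adjusted p = 1.2e-04). Of 22 phosphate and metal genes, 6 fell and 0 rose, with a median of -0.09 and a mean of -1.02 (camera adjusted p = 0.0203, adjusted p = 0.629 with an estimated correlation).

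Of 26 genes of the Na+ and K+ transport list in barley roots, 4 fell, 0 rose and 22 were not called (median -0.07, list adjusted p = 0.33). Genes with a potassium channel tetramerisation domain, such as MLOC_76596, are among the members. The K+ transporter gene MLOC_17989 (chromosome 4, 510562758 to 510564839) fell from 1105 ± 111.0 to 499.6 ± 99 FPKM (log2 fold change -1.16, SE 0.14, adjusted p = 0.00173), and MLOC_71693 from 20.7 ± 1.4 to 8.73 ± 0.429 FPKM (-1.16, adjusted p = 5.2e-04; 0.214 with both tissues in 1 fit). MLOC_15580 fell as well (-1.04, adjusted p = 9.8e-04) but missed the fold threshold without salt replicate 3 (adjusted p = 0.00568), and the ankyrin-type channel gene MLOC_74879 fell (-1.40, adjusted p = 0.00206). The Na+/H+ exchanger genes MLOC_10701 (-0.08, adjusted p = 0.653), MLOC_14189 (-0.60, adjusted p = 0.00861) and MLOC_4602 (0.49, adjusted p = 0.108) were not called. Of 10 genes of the proton pump list, 5 of them inorganic pyrophosphatases by InterPro name, and 21 of the aquaporin list, 0 and 1 fell and none rose (list adjusted p = 0.811 and 0.113), and the aquaporin list was called as lower without salt replicate 1 (0.044).

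Of 42 lipid transfer list genes in barley roots, 7 rose and 3 fell (median 0.36, camera adjusted p = 1.5e-06, 0.527 with an estimated correlation). Names such as that of MLOC_33063 also cover inhibitors and seed storage proteins. MLOC_33063 (contig 3HL, 8514 to 9199) rose from 8.13 ± 1.72 to 178.6 ± 9.84 FPKM (log2 fold change 4.31, SE 0.14, adjusted p = 2.3e-06). Of 34 phenylpropanoid genes, 5 rose and 2 fell (median 0.56, adjusted p = 3.7e-06, 0.527 with an estimated correlation), with the O-methyltransferase gene MLOC_63575 rising (1.66) and MLOC_76018 falling (-2.59). Of 107 class III peroxidase genes, 12 rose and 4 fell (median 0.10, adjusted p = 0.0151, 0.745 with an estimated correlation). MLOC_54023 (chromosome 7, 48439116 to 48440699) rose from 3.21 ± 0.932 to 34.7 ± 2.1 FPKM (3.11, SE 0.17, adjusted p = 3.8e-05). Of 74 cell wall genes, 6 rose and 5 fell (6 and 6 adjusted over the list alone; median 0.12, adjusted p = 0.00822, adjusted p = 0.745 with an estimated correlation), and this list was not called without control replicate 2 (adjusted p = 0.0527). With membership by description alone the wall list lay below other genes and was not called (adjusted p = 0.186). The germin gene MLOC_16950 (chromosome 5, 32045808 to 32046894) rose from 217.2 ± 28.8 to 2546 ± 180.2 FPKM (3.55, SE 0.11, adjusted p = 2.3e-06), and the RING finger gene MLOC_54790 from 2.53 ± 0.59 to 78.2 ± 24.8 FPKM (4.46, SE 0.22, adjusted p = 1.8e-05). The Casparian list had 4 genes, of which 1 rose, too few for the list test.

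Stress and regulatory lists of barley roots moved with few called members. Of 55 glutathione transferase genes, 2 rose and 0 fell (median 0.11, camera adjusted p = 0.00706, 0.745 with an estimated correlation). MLOC_74611 rose from 8.85 ± 2.34 to 63.2 ± 3.86 FPKM (log2 fold change 2.73, SE 0.17, adjusted p = 6.0e-05). Of 29 LEA and dehydrin genes 1 rose and 0 fell (median 0.21, adjusted p = 0.00217, 0.745 with an estimated correlation), and of 33 senescence genes 1 rose and 0 fell (median 0.20, adjusted p = 0.00212, 0.527 with an estimated correlation). Of 40 WRKY genes 5 rose, among them MLOC_11088 (1.86), and 1 fell (median 0.10, adjusted p = 0.00742, 0.547 with an estimated correlation). Of 25 jasmonate genes 2 rose, among them MLOC_33809 (1.99), and 1 fell, the lipoxygenase gene MLOC_71275 (-1.80) (median 0.16, adjusted p = 0.0203, 0.629 with an estimated correlation). Of 46 genes of the NAC list 3 rose, among them MLOC_63743 (1.48), and 0 fell (median 0.08, adjusted p = 0.0316, 0.631 with an estimated correlation), a call that ended without control replicate 3 (0.0704). Without 5 look-alike members the median was 0.16 (adjusted p = 0.007, 0.533 with an estimated correlation). Of 170 heat shock genes 8 fell, among them the HSP70 gene MLOC_14228 (-2.53), and 0 rose (median -0.14, adjusted p = 0.0203, 0.745 with an estimated correlation). The 52 splicing factor genes and 36 genes of the AP2/ERF list had no called member and lay below other genes (medians -0.17 and -0.17, adjusted p = 0.0197 and 0.0478, 0.753 and 0.753 with an estimated correlation). Both of these calls ended without control replicate 2 (0.0511 and 0.162) or salt replicate 1 (0.0749 and 0.117), and that of AP2/ERF also without 8 genes that are not such factors (0.0522).

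Uncalled lists of barley roots held few called genes. Of 53 genes of the photosynthesis list, 24 of them plastocyanin-like, 2 rose and 3 fell (camera adjusted p = 0.399), of 51 ethylene, auxin and cytokinin genes 1 and 4 (0.939), of 124 genes of the pathogenesis-related list 5 and 2 (0.247) and of 107 MYB genes 1 and 1 (0.906). Of the 124, 84 matched only through names such as methionine, and the other 40, of which 5 rose and 1 fell, lay above other genes (median 0.39, adjusted p = 0.00341, adjusted p = 0.422 with an estimated correlation). In the osmolyte list 1 of 32 genes rose (0.196) and in the nitrogen list 1 of 19 (0.164). No gene was called among 45 abscisic acid genes (0.827), 23 reactive oxygen genes (0.351), 7 chlorophyll genes (0.305), 20 ribosomal genes (0.981), 37 bZIP genes (0.874, median 0.06 and mean -0.03), 136 cell division genes (0.42) and 43 housekeeping genes (0.665). Salt and control did not overlap in 5456 genes (36.0%), against 10% by chance.

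The fourth question is which genes change in the barley leaf. The germin gene MLOC_16950, the lipoxygenase genes LOX2.1 and MLOC_71275 and the ferritin gene MLOC_69295 rose. The Ole e 1 family genes MLOC_2910 and MLOC_78745 and 2 of 37 peroxidase genes fell. Few genes were called, 23 higher and 34 lower of 13238 tested, and 1779 had an unadjusted p below 0.05.

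The Ole e 1 family genes MLOC_2910 (chromosome 7, 75696958 to 75697875) and MLOC_78745 (chromosome 2, 589560229 to 589561169) fell in barley leaves from 67.4 ± 11.7 to 2.71 ± 0.0486 FPKM (log2 fold change -4.19, SE 0.20, adjusted p = 6.0e-05) and from 166.9 ± 42 to 9.46 ± 2.56 FPKM (-4.00, SE 0.26, adjusted p = 4.8e-04). The germin gene MLOC_16950, which also rose in roots, rose from 1.77 ± 1.05 to 31.9 ± 7.87 FPKM (log2 fold change 3.60, SE 0.30, adjusted p = 0.0032). The lipoxygenase genes LOX2.1 (MLOC_64972, chromosome 5, 3531572 to 3535793) and MLOC_71275, known for jasmonate synthesis, rose from 245.2 ± 97.3 to 1596 ± 292.7 FPKM (2.75, SE 0.27, adjusted p = 0.0105) and from 36.2 ± 12.3 to 160.4 ± 41.2 FPKM (2.14, SE 0.27, adjusted p = 0.022). The lipase gene MLOC_80878 (2.15, SE 0.28, adjusted p = 0.022) and the ferritin gene MLOC_69295 (1.68, SE 0.24, adjusted p = 0.0257) rose. The peroxidase genes MLOC_65225 (-2.22, adjusted p = 0.0257) and MLOC_79176 (-1.94, adjusted p = 0.0365) and the RING finger gene MLOC_60517 (-1.58, adjusted p = 0.0459) fell. LOX2.1 was not called without control replicate 2, salt replicate 1 or salt replicate 2 (adjusted p = 0.0816, 0.126 and 0.0678). Without control replicate 1, control replicate 2, salt replicate 1, salt replicate 2 or salt replicate 3 the adjusted p of MLOC_60517 was 0.124, 0.183, 0.276, 0.236 and 0.113. Of 16 named genes called in barley leaves, 3 stayed called whichever library was left out.

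Of 30 WRKY genes in barley leaves none was called (0 higher and 4 lower adjusted over the list alone), and the list lay below other genes (median -0.52, camera adjusted p = 6.3e-07, adjusted p = 0.745 with an estimated correlation). Of 37 class III peroxidase genes 2 fell and 0 rose (0 and 5 adjusted over the list alone; median -0.34, adjusted p = 0.00189, adjusted p = 0.527 with an estimated correlation). The 10 genes of the proton pump list had no called member (median -0.34, adjusted p = 0.0246, 0.745 with an estimated correlation). Of 25 genes of the AP2/ERF list 1 rose and 0 fell (1 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.044, adjusted p = 0.843 with an estimated correlation). Lists above other genes without called members were 20 ribosomal genes (median 0.26, adjusted p = 0.0136, adjusted p = 0.865 with an estimated correlation) and 27 osmolyte genes (median 0.18, adjusted p = 0.0244, adjusted p = 0.833 with an estimated correlation). Others were 98 cell division genes (median 0.11, adjusted p = 0.0477, adjusted p = 0.853 with an estimated correlation) and 51 splicing factor genes (median 0.16, adjusted p = 0.0484, adjusted p = 0.955 with an estimated correlation). Without control replicate 3 the adjusted p was 0.45 for peroxidases, 0.118 for proton pumps, 0.475 for ribosomal genes, 0.0527 for osmolytes, 0.653 for splicing factors and 0.0863 for AP2/ERF genes. The AP2/ERF call also ended without control replicate 2 (0.0629), salt replicate 1 (0.0535), salt replicate 2 (0.0507) or salt replicate 3 (0.0621). With look-alike members dropped neither the AP2/ERF list (17 genes, 0.207) nor the proton pump list (16 genes, 0.0596) was called. The proton pump call ended without salt replicate 2 (0.0512), the splicing call without salt replicate 1 (0.105), and the cell division call without control replicate 1 (0.207), control replicate 2 (0.0942) or salt replicate 1 (0.0683).

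No member was called in barley leaves among 25 Na+ and K+ transport genes (list adjusted p = 0.475), 40 abscisic acid genes (0.0719), 19 genes of the aquaporin list (0.305), 13 chlorophyll genes (0.882) and 15 nitrogen genes (0.932). Nor was any called among 39 glutathione transferase genes (0.451), 165 heat shock genes (0.605), 36 genes of the NAC list (0.6), 28 bZIP genes (0.6), 28 genes of the lipid transfer list (0.911), 6 Casparian genes (0.997), 28 senescence genes (0.828) and 41 housekeeping genes (0.906). Of 25 LEA and dehydrin genes 1 fell (median -0.20, adjusted p = 0.0685), of 37 cell wall genes 1 rose (0.527), of 37 ethylene, auxin and cytokinin genes 1 rose (0.906) and of 12 phosphate and metal genes 1 rose (2 adjusted over the list alone; 0.902). Of 19 jasmonate genes 3 rose, with a median of -0.16 and a mean of 0.21 (0.781). The lists of photosynthesis (93 genes, median 0.06, 0.767), pathogenesis-related proteins (97 genes, 0.906) and 23 reactive oxygen genes (0.909) had 1 member higher each when adjusted over the list alone, and those of 29 phenylpropanoid genes (median -0.17, 0.41) and 85 MYB genes (0.781) 1 member lower each. Of the 97, 74 matched only through names such as methionine, and the other 23 lay below other genes (median -0.50, adjusted p = 0.00869, adjusted p = 0.675 with an estimated correlation). Single libraries moved several of these lists: without control replicate 3 the photosynthesis (1.3e-09), cell wall (1.7e-06), lipid transfer (0.00143) and phenylpropanoid (0.0333) lists were called above other genes. Without control replicate 1 the photosynthesis list was called below other genes (0.0189), and the abscisic acid list was called lower without control replicate 1 (0.0387) or salt replicate 1 (0.0491). The phenylpropanoid list was called lower without control replicate 2 (0.013), and the LEA list without control replicate 2 (0.00475), salt replicate 2 (0.0328) or salt replicate 3 (0.0435).

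In barley leaves 2671 genes (20.2%) had no overlap between salt and control, against 10% by chance. The count of 57 calls was 593 without control replicate 3, the library with 23.4% of fragments on its 10 largest genes, and 3 to 5 without any other single library.

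**Figure D2:**
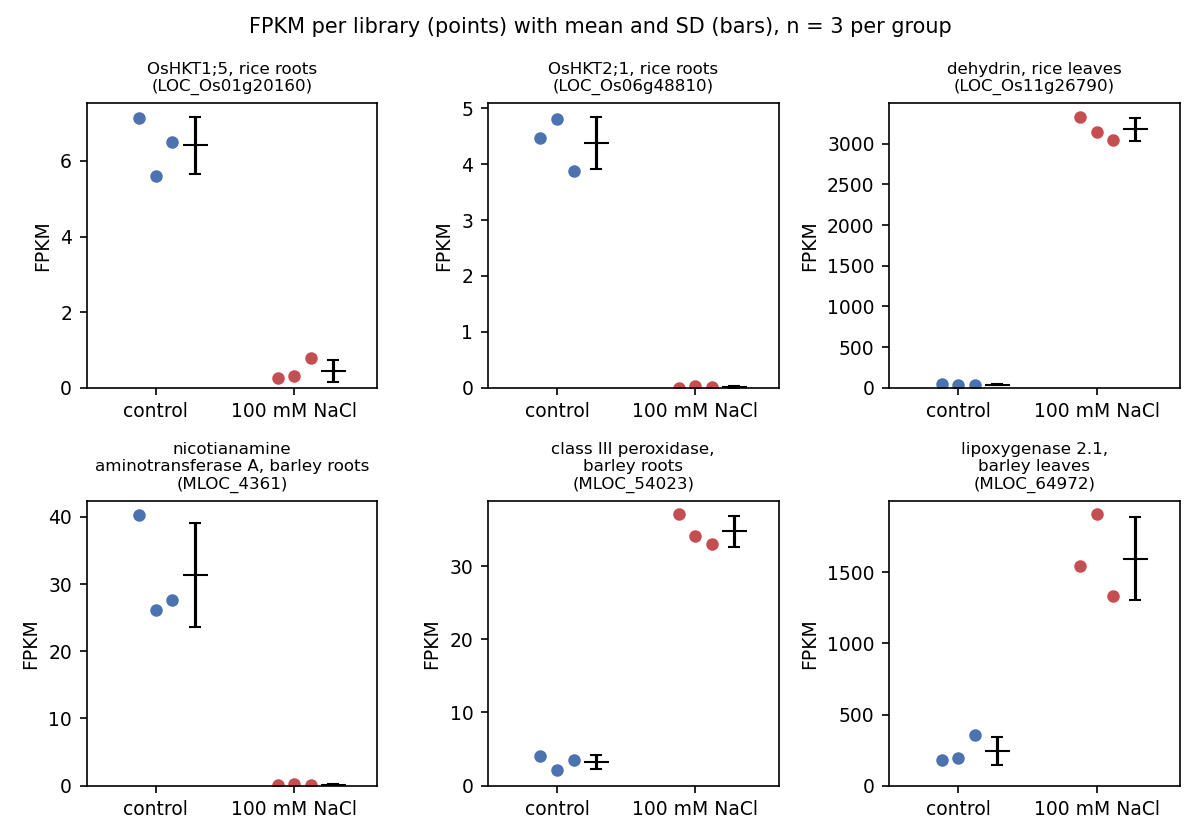
FPKM of 6 genes in each control and salt library of the named tissue, with mean and SD (n = 3). OsHKT1;5, OsHKT2;1 and NAAT-A are lower in salt, and the dehydrin, peroxidase and LOX2.1 genes are higher.

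**Figure D3:**
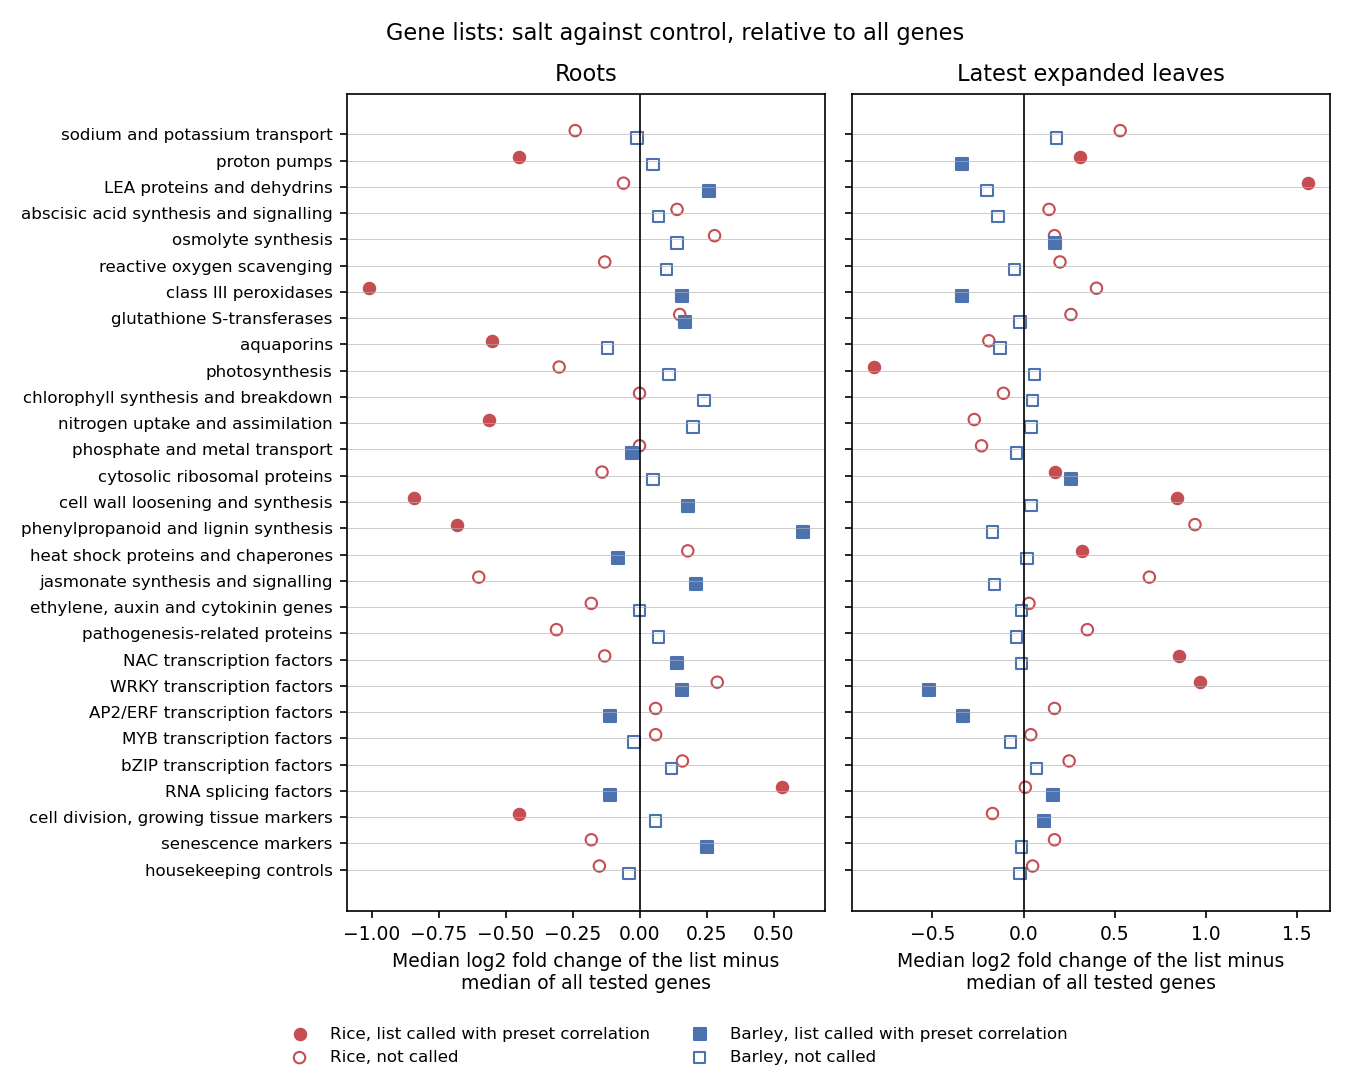
Median log2 fold change (salt against control) of each gene list minus the median of all tested genes, for rice and barley in roots and in leaves. Filled points mark lists called with the preset correlation, and the wall, peroxidase and phenylpropanoid lists of the species lie on opposite sides of 0 in roots.

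The fifth question is whether the salt effect differs between root and leaf within a species. The interaction tests shoot minus root directly and called 6212 of 20196 rice genes, 4942 with a higher and 1270 with a lower change in leaves, and 573 of 15547 barley genes, 219 and 354. The barley split turned to 350 and 300 without shoot control replicate 1 and was 295 and 771 without shoot control replicate 3. With median-ratio scaling the rice split was 3298 and 2421, and with quantile normalization 2932 and 2938. The jacalin gene LOC_Os01g24710 fell in rice roots from 696.2 ± 54 to 189.5 ± 30.2 FPKM (-1.88) and rose in leaves, a difference of 8.60 (SE 0.32, adjusted p = 5.3e-08). The antiporter gene LOC_Os05g31730 differed by -4.93. Of 15682 rice genes tested in both tissues, 515 rose in both against 226.3 expected for independent calls, and 220 fell in both against 68.0. In opposite directions 289 fell in roots and rose in leaves against 310.2, and 35 rose in roots and fell in leaves against 49.6. Of 11886 barley genes, 5 rose in both (0.2 expected), 3 fell in both (0.2 expected) and 1, the lipoxygenase gene MLOC_71275, fell in roots and rose in leaves (0.1 expected). In barley NAAT-A (MLOC_4361) and the dioxygenase gene MLOC_80402, listed at 0 in leaves, differed by 4.80 and 5.41, and MLOC_33063 of the lipid transfer list by -4.45.

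**Figure D4:**
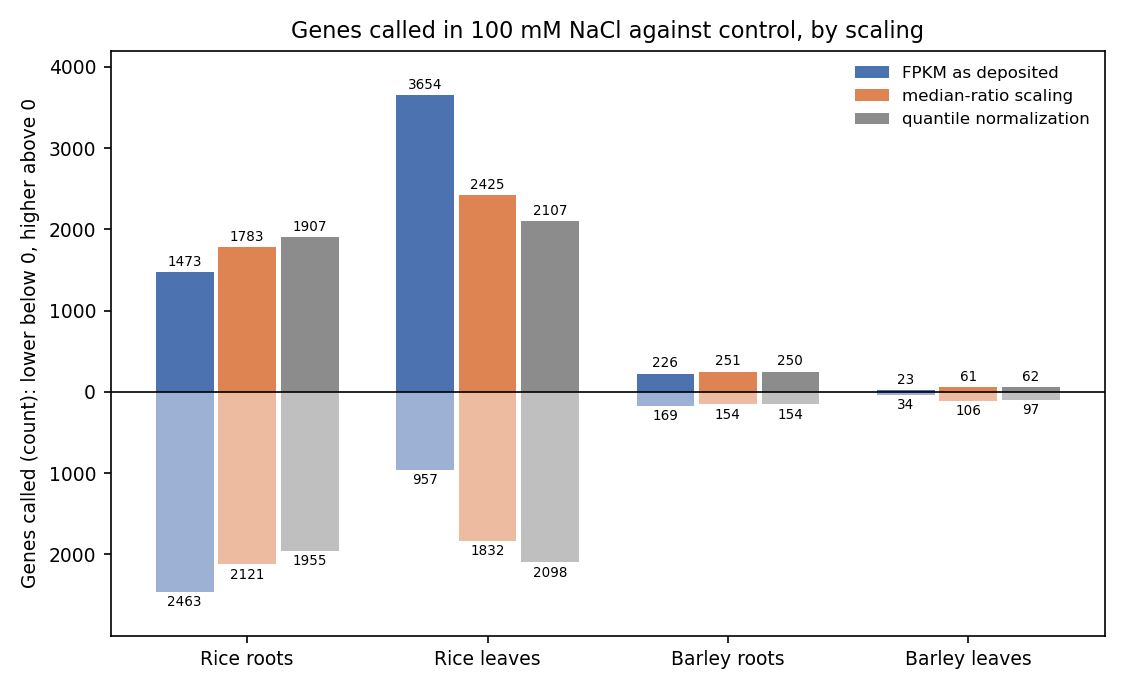
Number of genes called higher and lower in salt for each species and tissue with values as deposited, with median-ratio scaling and with quantile normalization. The split of rice leaves moves most between the scalings.

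The sixth question is whether the 2 species change in matching genes. Among 1196 gene pairs tested in roots the log2 fold changes had a Pearson correlation of 0.15 (Spearman 0.13), and among 1159 pairs in leaves -0.03 (Spearman 0.01). In roots 162 rice and 11 barley members were called, 4 pairs in the same direction (0.8 expected) and 1 in opposite directions. The pairs LOC_Os10g39890 and MLOC_50963 of the Ole e 1 family (-3.16 and -1.89), LOC_Os04g57860 and MLOC_60257, endoglucanase genes (-4.00 and -2.44), and LOC_Os03g12110 and MLOC_37381, homocysteine methyltransferase genes (-1.07 and -1.06), fell in both species. The leucoanthocyanidin dioxygenase genes LOC_Os01g70930 and MLOC_55123 rose in both (1.51 and 1.30), and the phospholipase C genes LOC_Os03g30130 and MLOC_71887 fell in rice and rose in barley (-1.70 and 1.02). In leaves 219 rice and 2 barley members were called, and 2 pairs matched in direction (0.2 expected). They were the amine oxidase genes LOC_Os04g57560 and MLOC_37328 (-1.16 and -1.55) and the alpha-galactosidase genes LOC_Os10g35110 and MLOC_1587 (2.63 and 1.31).

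List medians of the species were compared by permutation. In roots the median of class III peroxidases was lower in rice by 1.22 (rice minus barley -1.22, BH adjusted p = 5.7e-05), that of phenylpropanoid genes by 1.35 (-1.35, adjusted p = 1.3e-04) and that of cell wall genes by 1.06 (-1.06, adjusted p = 5.7e-05). The barley wall list changes direction with membership by description alone, and this comparison was not run with that membership. Splicing factors were higher in rice roots (0.60, adjusted p = 5.7e-05). In leaves rice was higher for LEA proteins and dehydrins (2.08, adjusted p = 9.5e-05) and WRKY factors (1.81, adjusted p = 5.7e-05) and lower for photosynthesis (-0.56, adjusted p = 5.7e-05, and -0.83 without plastocyanin-like genes, adjusted p = 6.3e-05). The Na+ and K+ transport list did not differ in roots (-0.28, adjusted p = 0.18), and in leaves it differed only before the all-gene medians were taken off (0.67, adjusted p = 0.00346 and 0.164). Of 28 lists compared in roots 14 differed, and of 29 in leaves 22, and relative to the all-gene medians 12 and 11 did so. The pairing through Arabidopsis covers only part of the genes, and barley descriptions are sparse, so list members of the species are not matched gene by gene.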

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

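The tests on scaling in rice leaves, on genes of barley leaf control replicate 3 that lie near the controls and on regrouped libraries were chosen only after the result was seen, and so were the species comparisons relative to all-gene medians. Values expected if a cause held were written down before the other tests ran, with the exception given below.

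In rice leaves 79.2% of called genes were higher in salt. Thinned libraries argue against depth as the cause, because 79.1% were higher with all libraries thinned to the shallowest. A shift of all genes by the authors' normalization stays open: 57.0% were higher with median-ratio scaling and 50.1% with quantile normalization, but both scalings centre the genes (all-gene median 0.321 before, -0.007 and -0.091 after), so these shares decide nothing. Loss of reads from the 100 largest genes, which held 44.5 to 47.4% of fragments in control and 21.4 to 28.6% in salt, also stays open: without them in the totals the all-gene median was -0.104 and 50.8% of 4312 calls were higher. A real excess of leaf genes that rise in salt was not tested and stays open as well.

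In barley leaves 57 genes were called with control replicate 3 and 593 without it (128 higher, 465 lower). A median root share of 0.000% over 492 root genes argues against root RNA in that library, and 598 calls without it in thinned libraries, with at most 5 without another, argue against depth, a test that replaced, before its result was seen, the bare question whether this library had the fewest fragments of its 6 (28.1 M, which it had). A plant like those of the 3 salt libraries is argued against by sets of 593 genes in which 93 to 106 lay nearer the controls than 0.25 of the way to salt in control replicate 3 and 1 to 7 in a left-out salt library, and its correlations were 0.965 to 0.967 with the salt libraries (0.991 to 0.993 among themselves) and 0.962 to 0.963 with the other controls. Its photosynthesis share (32.27%) lay above the salt libraries (22.85 ± 0.07%) and the other controls (16.93% and 19.59%), so it matched neither group. A wrong label on a salt-treated plant unlike these 3 could still explain the median position of 0.77 between control (0) and salt (1), quartiles 0.48 to 1.07 over 593 genes, which met the value written beforehand, and it stays open beside a true difference between plants.

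Rice had 3936 and 4611 genes called in roots and leaves, barley 395 and 57. The residual SD of barley was 0.88 times that of rice in leaves and 0.79 times in roots, which argues against larger spread as the whole cause, although control replicate 3 lowered the barley leaf count from 593 to 57. Rice root libraries thinned to 23.6 M fragments still gave 3963 calls, and rice salt leaf libraries (23.3 to 27.3 M) were shallower than every barley leaf library (28.1 to 51.7 M), which argues against depth. An absolute log2 fold change above 1 was reached by 2.8% of barley root and 2.9% of barley leaf genes, against 20.3% and 28.5% in rice, but a call requires such a change, so these shares largely restate the counts and leave smaller changes in barley open. Whether species, tolerance or the state of the plants after 7 d lies behind this was not tested and stays open.

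Every other grouping of the 6 libraries of a table into 3 and 3 gave 0 gene calls, but 10 groupings are too few for a share under 0.05. The real grouping alone, 1 of 10, reached its count in every table. For called lists, with adjustment within a table, the real and the highest other count were 8 and 9 in rice roots (3 of 10 groupings gave as many), 7 and 12 in rice leaves (4 of 10), 14 and 8 in barley roots (1 of 10) and 5 and 10 in barley leaves (9 of 10).

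The salt effect differed between tissues in 6212 rice and 573 barley genes. Over 100 groupings within tissues, each turned to the direction nearest the real one, only the real one reached these counts (next 3299 and 398). Regrouping also removes salt effects, so it cannot test this difference. Of the named results, 118 of 136 in rice and 49 of 90 in barley belonged to genes with a called difference.

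Shoot minus root log2 fold changes in rice were 8.60 for the jacalin gene LOC_Os01g24710. They were 7.15 for the glycosyltransferase gene LOC_Os01g02900, 7.12 for the methyltransferase gene LOC_Os06g13560 and 6.99 for the AWPM-19-like gene LOC_Os05g31670. The fasciclin gene LOC_Os05g48900 had 6.85 (SE 1.54, adjusted p = 0.00378). The ferric-chelate reductase gene LOC_Os04g48930 had -6.27 and was listed at 0 in roots. The MYB gene LOC_Os05g50340 had -5.72 and the tesmin-like gene LOC_Os05g51040 -5.68 (SE 1.38, adjusted p = 0.00597). The aspartic proteinase gene LOC_Os12g39360, listed at 0 in roots, had -5.22, which repeats the leaf decrease, and the antiporter gene LOC_Os05g31730 -4.93.

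In barley the major facilitator genes MLOC_56629 and MLOC_70963 had shoot minus root values of 5.77 and 4.42. The dioxygenase genes MLOC_80402 and MLOC_1079 had 5.41 and 4.78, and NAAT-A (MLOC_4361) had 4.80. These 5 genes were listed at 0 in leaves, so the values repeat the decrease in roots. MLOC_33063 of the lipid transfer list had -4.45 and the RING finger gene MLOC_54790 -4.44. The Ole e 1 genes MLOC_2910 and MLOC_78745 had -4.23 and -4.00, values of the leaf decrease, since MLOC_78745 was listed at 0 in roots and MLOC_2910 at 0 and 0.0248 FPKM, and the wall-associated kinase gene MLOC_9378 -3.82.

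Rice minus barley list medians in roots follow, with BH adjusted p of the permutations as measured and then relative to all genes, where 1.0e-05 is the smallest unadjusted p they can give. LEA proteins and dehydrins gave -0.37 (0.00958, 0.0287), class III peroxidases -1.22 (5.7e-05, 7.1e-05), photosynthesis -0.47 (0.00588, 0.0146) and nitrogen -0.81 (6.8e-04, 0.00103). Cell walls gave -1.06 (5.7e-05, 1.3e-04), phenylpropanoids -1.35 (1.3e-04, 7.1e-05), heat shock proteins 0.22 (5.7e-05, 7.1e-05) and jasmonate -0.86 (4.4e-04, 2.6e-04). Pathogenesis-related proteins gave -0.43 (5.7e-05, 7.1e-05), splicing factors 0.60 (5.7e-05, 7.1e-05), cell division -0.57 (5.7e-05, 7.1e-05) and senescence -0.49 (0.00213, 0.00701).

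In leaves the same differences were 2.08 for LEA proteins and dehydrins (9.5e-05, 1.7e-04), 1.06 for class III peroxidases (4.4e-04, 0.00672) and -0.56 for photosynthesis (5.7e-05, 7.1e-05). They were 1.12 for cell walls (2.7e-04, 0.00336), 1.43 for phenylpropanoids (7.3e-04, 0.00171), 0.62 for heat shock proteins (5.7e-05, 7.1e-05) and 0.70 for pathogenesis-related proteins (5.7e-05, 1.9e-04). NAC factors gave 1.18 (9.5e-05, 4.5e-04), WRKY factors 1.81 (5.7e-05, 1.9e-04) and AP2/ERF factors 0.81 (6.8e-04, 0.0351). A difference is given here only where both adjusted p were below 0.05, a requirement chosen after the shift of rice leaves had been seen.

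With look-alike members dropped, the root difference of photosynthesis was 0.25 (0.176, 0.129), so the -0.47 above was not carried by genes of photosynthesis, and the leaf difference of AP2/ERF factors was 0.87 (0.0134, 0.0738). The leaf difference of photosynthesis was -0.83 (6.3e-05, 8.1e-05), that of NAC factors 1.30 (6.3e-05, 0.00225) and that of pathogenesis-related proteins 1.87 (0.0109, 0.0323), and in roots the last was -0.82 (3.9e-04, 0.00134), nitrogen -0.83 (3.7e-04, 6.2e-04) and senescence -0.57 (3.9e-04, 0.00156). Proton pumps then differed in roots (-0.60, 0.0043 and 0.00644) and leaves (0.86, 0.00242 and 0.0333), and NAC factors in roots (-0.40, 0.011 and 0.0312).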

How the results depend on the processing

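Rice root and barley root counts moved without the fold threshold and with voom on recovered fragments, which changes the filter, the genes tested, the values and their scaling along with the test. The rice leaf count stayed within a factor of 1.5 under every setting, and the barley leaf count moved with most settings. The count-only alternatives planned were not run, because no counts were in use. Without a fold threshold 10058 genes were called in rice roots and 2213 in barley roots. With voom on recovered fragments, an added alternative, the counts were 6246 in rice roots, 832 in barley roots and 300 in barley leaves. The authors' own calls numbered 6854 (3071 higher, 3783 lower) in rice roots, 6348 (3798 and 2550) in rice leaves, 1046 (671 and 375) in barley roots and 553 (157 and 396) in barley leaves, and they included 3671 of 3936, 3642 of 4611, 383 of 395 and 57 of 57 calls made here, all in the same direction. In barley leaves quantile normalization gave 159 calls, median-ratio scaling 167 (61 higher, 106 lower), no filter 2, an adjusted p below 0.01 gave 3, and both tissues in 1 fit gave 250. The cause of these moves was not tested.

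Leaving out 1 library gave 3793 to 4191 calls in rice roots and 3820 to 5120 in rice leaves (4391 without salt replicate 1). In barley roots it gave 383 to 440, and in barley leaves 593 without control replicate 3 and 3 to 5 without another. The interaction counts ran from 5778 to 6716 in rice and from 409 to 1066 in barley, the last without shoot control replicate 3. The cause was not tested.

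The labels do not state whether replicate numbers pair the samples. With replicate number as a block the counts were 3948 in rice roots, 4793 in rice leaves, 406 in barley roots, 102 in barley leaves, 6051 and 389 for the interactions of rice and barley, and 9, 10, 14 and 7 lists were called in the 4 tables against 8, 8, 14 and 8. The block added jasmonate in rice roots (0.0474) and phenylpropanoids (0.011) and pathogenesis-related proteins (0.0159) in rice leaves, and it ended the barley leaf call of cell division (0.0584). Changes of libraries with the same number correlated at -0.079, 0.072 and 0.137 in rice roots, -0.128, -0.181 and -0.106 in rice leaves, 0.177, 0.128 and -0.041 in barley roots and -0.059, 0.102 and -0.031 in barley leaves. The cause was not tested.

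With an estimated correlation all list calls ended, 8, 8, 14 and 8. The cell wall list of barley roots, above other genes with an adjusted p of 0.00822, was below them and not called with membership by description alone (0.186). That membership also ended the barley root calls of heat shock (0.0663), NAC (0.294) and splicing lists (0.431), the barley leaf calls of osmolytes (0.0542) and splicing (0.184) and the rice leaf call of cell walls (0.0542). It added pathogenesis-related proteins in rice leaves (0.046), osmolytes (0.0087) and cell division (0.018) in barley roots and lipid transfer in barley leaves (0.00876), all above other genes. By description alone, 6 of the 14 lists called in barley roots (LEA, peroxidase, glutathione transferase, WRKY, AP2/ERF and lipid transfer) and 3 of the 8 in barley leaves (peroxidase, WRKY and AP2/ERF) had too few members to be tested. With look-alike members dropped, the photosynthesis list of rice roots turned from below other genes and uncalled (0.215) to called above them (0.00341). That membership also called pathogenesis-related proteins above other genes in rice leaves (0.0496) and barley roots (0.00341) and below them in barley leaves (0.00869), and ended the calls of AP2/ERF in barley roots (0.0522) and leaves (0.207) and of proton pumps in barley leaves (0.0596). With an estimated correlation none of these was called. The photosynthesis list of barley leaves ran from 1.3e-09 (above other genes, without control replicate 3) to 0.986 (without salt replicate 2), and was called below other genes without control replicate 1 (0.0189). The phenylpropanoid and lignin list of barley leaves ran from 0.013 (below, without control replicate 2) to 0.575 (without salt replicate 1), and was above other genes without control replicate 3 (0.0333). The cause was not tested.

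No named gene was reversed under any setting. Calls held whichever library was left out for 68 of 70 named genes in rice roots, 62 of 66 in rice leaves, 38 of 41 in barley roots and 3 of 16 in barley leaves, and under the other alternatives for 68, 63, 35 and 2. In barley leaves 14 of the 16 were lost with no filter and 13 at an adjusted p below 0.01.

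Rice and barley pairs called in the same direction in roots were 2 with a mean of at least 5 FPKM (0.5 expected), 36 without a fold threshold (31.1 expected) and 3 to 5 with 1 library left out. In leaves they were 0 with no filter, 0 at an adjusted p below 0.01, 5 with voom (1.1 expected) and 0 to 3 with 1 library left out, 0 without barley control replicate 1 and 3 without barley control replicate 3. Counts this small move by single pairs, and the cause was not tested.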

Other observations

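Among Gene Ontology terms, genes that fell in rice roots were enriched for the extracellular region (69 genes against 25.4 expected, BH adjusted p = 8.6e-13 by Fisher tests), peroxidase activity (52 against 17.6, 3.5e-11) and plant-type cell wall organization (18 against 2.9, 2.2e-10). Further terms among them were cellulose biosynthetic process (15 against 4.0, 1.1e-04), nucleosome (28 against 11.8, 3.5e-04), lipid transport (21 against 6.7, 4.2e-05) and water transport (7 against 1.3, 0.00248). Genes that rose there were enriched for the chloroplast thylakoid membrane (27 against 7.9, adjusted p = 1.4e-06), the nucleoid (9 against 1.1, 2.4e-05) and photosynthesis (10 against 2.5, 0.00374), among them the photosystem I gene LOC_Os05g48630 (log2 fold change 3.50). In rice leaves the higher genes were enriched for response to stress (78 against 33.2, 9.5e-13), carbohydrate metabolic process (118 against 68.8, 6.7e-08), peroxisome (38 against 22.1, 0.0158), response to cold (49 against 31.4, 0.0235) and response to salt stress (67 against 46.7, 0.0345). The lower genes were enriched for plastoglobule (10 against 1.9, 0.00137), thylakoid (19 against 6.4, 0.00233) and light harvesting (5 against 0.8, 0.0465). In barley roots the higher genes were enriched for peroxidase activity (13 against 1.9, 6.1e-05), response to oxidative stress (12 against 2.2, 5.8e-04) and lipid transport (6 against 0.8, 0.0203), and the lower genes for oxidoreductases that use 2-oxoglutarate (7 against 0.7, 0.00187). The numbers of enriched terms, higher and lower, were 7 and 45 in rice roots, 25 and 6 in rice leaves, 5 and 3 in barley roots and 0 and 0 in barley leaves, where the lowest adjusted p over 498 terms was 1. With both directions together they were 42, 27, 12 and 0.

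Peroxidase activity was enriched among lower genes in rice roots and among higher genes in barley roots, and so was lipid transport. All 18 photosynthesis list genes that fell in rice roots were plastocyanin-like. Of the other 24, 7 rose and 0 fell, and the photosynthesis term was enriched among genes that rose.

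In rice leaves the 10 largest genes held 21.3 to 24.0% of fragments in control and 8.6 to 12.9% in salt. Rice salt leaf replicate 1 had a mean correlation of 0.928 with its group, the others 0.949 and 0.938. Barley control leaf replicate 3 held 32.27% of fragments on photosynthesis genes, the other controls 16.93% and 19.59%, and the salt libraries 22.85 ± 0.07%. The positions of barley leaf controls 1 and 2 between control and salt were 0.33 and 0.20, and those of the barley root controls 0.06, 0.14 and 0.02.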
